A study of Homo sapiens with 6 samples.

How the data were processed

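RNA of HTR-8/SVneo cells, an immortalised human trophoblast line, was sequenced 48 hours after transfection with a miR-26a-5p mimic or with a negative control (miR-NC). Each group has 3 libraries in the labels. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries with a dual-mode mRNA kit. The deposited table holds expected counts (estimated counts) made by the authors, not scaled to depth, for 22968 gene rows with numeric gene identifiers and 23841 circular RNA rows. Of its nonzero values, 5.44% were not whole at a tolerance of 1e-06, so the expected counts were rounded to whole numbers before testing. Per the submitters' processing notes, HISAT, Bowtie2 and GRCh38 were used. Their versions, the counting tool, the annotation, the filters and the use of strand are not given in the sources used here. Reads shared by overlapping genes, antisense partners or near-identical copies can therefore be split in ways that are not known. The lowest nonzero value of a circular RNA row was 10, against 0.01 for a gene row, so the circular RNA rows had passed a minimum that the gene rows had not. Circular RNA rows held 15.1% to 20.5% of each library's total and were left out of the library sizes and the main test.

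Gene identifiers were matched to RefSeq names, and 22910 of the 22968 gene rows had a match. Gene coordinates are those of RefSeq on GRCh38. Target sites were searched in the longest annotated 3' UTR (at least 50 bases) of each gene in GENCODE release 29, also on GRCh38, and 15357 genes had one. A gene with no annotated 3' UTR was counted as not searched. Site classes were the usual ones: an 8mer pairs with bases 2 to 8 of the microRNA and has an A after the match, a 7mer-m8 lacks that A, a 7mer-A1 lacks the pair at base 8, and a 6mer lacks both. Each gene was put in its best class.

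Gene-row totals ran from 3278495 to 6141448 per library. At these depths a count of 0 allows up to 0.489 to 0.915 CPM scaled to the library's gene-row total, the level of 3 reads, for counting error only. CPM values of genes are scaled by TMM unless the text says otherwise. Libraries were compared by a chi-square test of their counts over genes with at least 40 reads in the pair. The comparison was checked on simulated data, in which a doubled subset of a library gave 0.571 per degree of freedom and a separate draw gave 0.976. Control libraries 1 and 3 differed by less than the sampling noise, and their mean was counted as 1 sample. Mimic library 2 matched a mixture of mimic libraries 1 and 3 within sampling noise and was left out. The test thus used 4 independent libraries, 2 per group. The design fixed before the data were examined had all 6 libraries, and that fit is given as an alternative. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

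Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, two-sided, with TMM scaling, the filterByExpr filter, a robust prior and Benjamini-Hochberg adjustment over all 13758 genes tested, at a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. The 32 gene lists, all fixed before the data were examined, were tested with camera in limma 3.58.1, adjusted over the lists. The correlation between genes was preset at 0.01, and camera was run again with an estimated correlation. The fry test of limma was run alongside, also adjusted over the lists. Within each list, p-values were also adjusted over the list alone. Site classes were compared with genes lacking a site by the difference in median log2 fold change, with 100000 permutations, two-sided, and a 95% bootstrap interval from 2000 resamples. The seed word was ranked among 420 words, itself and 419 others of the same base composition. In counts simulated for 13539 genes, with 200 genes changed, the edgeR test recovered 44% of 2-fold and 98% of 4-fold changes with 8 false calls. Every simulated gene had the spread usual for its count level, with no further scatter between genes. Changed genes were drawn only from those with at least 200 reads in all. Recovery in the real counts can therefore be lower, and some genes with fitted changes above 4-fold were not called there. A simulated shift of -0.2 in 8mer genes was recovered as -0.174 with the seed word at rank 1, and with no shift the word stood at rank 207.

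Named genes followed a rule fixed before the data were examined. It took up to 10 called genes in each direction with an average log2 CPM of at least 2 and non-overlapping groups, unnamed genes and pseudogenes left out, 15 fixed genes, up to 4 members of each list with the smallest p, and up to 8 called lower genes with an 8mer site and an average log2 CPM of at least 4. No gene met the last part. The unnamed LOC genes and the genes with an adjusted p under 0.1 were chosen after their values were seen, as were other list members named as passing over their list alone. Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile), limma-voom, DESeq2 1.42.0, no filter or a stricter one (at least 1 CPM in 3 libraries), a non-robust prior, a replicate block, each library left out, the shortest 3' UTR, length-matched genes, genes with an average log2 CPM of at least 4 only, and words in the coding sequence. The fit of all 6 libraries was the planned main fit, and the choice of 4 independent libraries was made after the data were seen. Keeping mimic library 2 as a separate library or the circular RNA rows, and leaving out control libraries 1 and 3 together, were also added then. So were an adjusted p under 0.1, unadjusted calls, single-library site tests and list medians in library pairs that share none. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the site tests and plots.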

Results

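The transcriptome of HTR-8/SVneo cells, an immortalised line from invasive trophoblast of the early human placenta, was measured 48 hours after transfection with a mimic of miR-26a-5p or with a scrambled control. The series asks which genes the mimic changes, with a focus on invasion and migration. Each group had 3 libraries. Gene-row totals were 6141448, 3845531 and 5594402 reads in control libraries 1 to 3, and 3278495, 3375936 and 5247782 reads in mimic libraries 1 to 3. The mature microRNA itself was not measured in these libraries.

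The 6 libraries did not hold 6 separate sets of reads. Control libraries 1 and 3 differed by less than the sampling noise, with a chi-square per degree of freedom of 0.584 against 3.84 for control libraries 1 and 2. All 15187 nonzero values examined in control 3 were even numbers, against 46.3% in control 1. Control libraries 1 and 3 were therefore counted as 1 sample. Mimic library 2 matched a mixture of 41% mimic 1 and 59% mimic 3 with a chi-square per degree of freedom of 0.426, and the best of 6 other mixtures gave 3.72. Of 1078 genes at 0 in both mimic 1 and mimic 3, 2 were above 0 in mimic 2 and 777 in control 1. Mimic 2 was left out, so that the values below rest on n = 2 libraries per group.

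**Figure D1:**
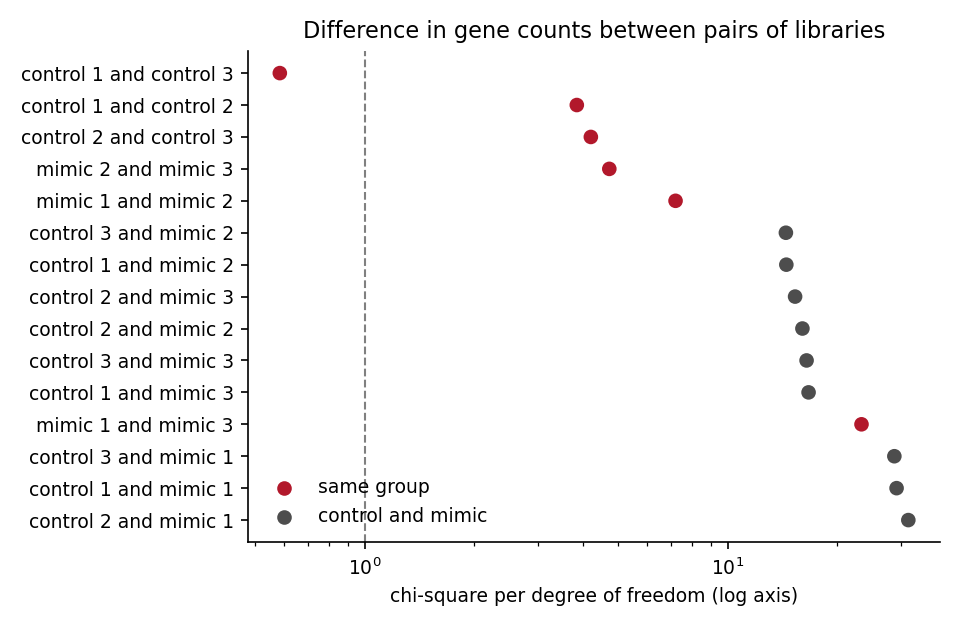
Chi-square per degree of freedom of gene counts for each pair of the 6 libraries, on a log axis, with pairs of the same group in red and pairs of a control and a mimic library in grey. The dashed line marks 1, the value for separate draws from the same RNA, and control libraries 1 and 3 lie below it at 0.584.

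LCP1, which encodes the actin-bundling protein L-plastin, rose in the mimic libraries from 3.31 ± 1.29 to 73.3 ± 10.8 CPM (SD, n = 2). Its log2 fold change was 4.52 ± 0.33 (SE), with an adjusted p of 0.0226 in edgeR's quasi-likelihood test. The gene lies on chromosome 13 from 46125923 to 46182177 and had no miR-26a site in its 3' UTR, and it overlaps the pseudogene RN7SL288P. The other called genes were long noncoding RNAs known only by identifier, named after their values were seen. LOC105370363 on chromosome 13 rose from 3.17 ± 0.37 to 67.1 ± 10.8 CPM, and LOC124901083 on chromosome 5 from 1.56 ± 0.03 to 29.8 ± 2.89 CPM (SD, n = 2). LOC124904632 on chromosome 19 rose from 24.3 ± 5.55 to 176 ± 24.6 CPM (SD, n = 2) and overlaps the annotated RAB11B-AS1, so its reads may be shared with that gene. In all, edgeR called 4 genes higher and 0 lower of 13758 tested. At an unadjusted p under 0.05 it gave 1343 higher and 1144 lower, 2487 genes where chance gives 688. With circular RNA rows kept it gave 684 higher and 719 lower gene rows, and without control 2 no excess over chance remained. At the adjusted threshold, DESeq2 called 143 higher and 136 lower and limma-voom 3 higher and 0 lower. The count was 0 higher and 0 lower without control 2, 952 and 979 without mimic 1, 2204 and 2362 without mimic 3, and 1900 and 1764 with all 6 libraries counted as separate. All 4 calls ended without control 2 or with circular RNA rows kept, and that of LOC124901083 ended with limma-voom (adjusted p 0.0672). Their log2 fold changes stayed near those above: without control 2 they were 4.91 for LCP1, 4.50 for LOC105370363, 4.24 for LOC124901083 and 3.09 for LOC124904632, with circular RNA rows 4.45, 4.32, 4.16 and 2.78, and LOC124901083 had 4.15 with limma-voom.

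Genes reported elsewhere as miR-26 targets lay lower in the mimic libraries as a group. Of 39 tested, 27 had a log2 fold change below 0, 23 were lower in both mimic libraries, and the median was -0.29. With p adjusted over the list alone, 14 fell and 2 rose, and over all genes tested none passed. CDK6, a kinase of the G1 phase of the cell cycle, went from 509 ± 93.1 to 154 ± 54.6 CPM (SD, n = 2), a log2 fold change of -1.72 ± 0.28 (SE). PLOD2, a collagen-modifying hydroxylase, had -1.36 ± 0.21, and LARP1, a regulator of ribosomal protein mRNAs, had -0.95 ± 0.17. Those that rose over the list alone were the transcription factor E2F2, at 1.96 ± 0.32, and the DNA methyltransferase DNMT3B, at 0.89 ± 0.27. The list was called lower by camera (adjusted p 0.00034), and its adjusted p = 0.882 with an estimated correlation.

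Of the fixed target genes, CDK6, PTEN, HMGA2 and CTDSP2 fell over the list alone, and EZH2, CTDSP1, CTDSPL, CCNE1 and SMAD1 did not pass. PTEN, a phosphatase that opposes PI3K, had a log2 fold change of -0.52 ± 0.16 (SE), and the chromatin protein HMGA2 had -1.22 ± 0.38. The phosphatase CTDSP2 had -0.86 ± 0.24, CTDSP1 0.20 ± 0.31 and CTDSPL 0.44 ± 0.19. EZH2, the histone methyltransferase of PRC2, had 0.76 ± 0.31, with 34.4 and 40.1 CPM in the controls and 82.5 and 44.9 CPM in mimic 1 and mimic 3. CCNE1 had -0.13 ± 0.29 and SMAD1 -0.19 ± 0.23. Adjusted p-values of these genes over all genes tested ran from 0.119 to 0.841 in edgeR, so none passed. Among invasion and adhesion genes, MMP2 had -0.24 ± 0.29, MMP9 -0.58 ± 0.36, CDH2 -0.56 ± 0.17 and VIM -0.46 ± 0.23, none past the threshold. HLA-G had between 0 and 7 reads in each of the 6 libraries, near the limit of detection, and CDH1 had no row in the deposited counts.

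**Figure D2:**
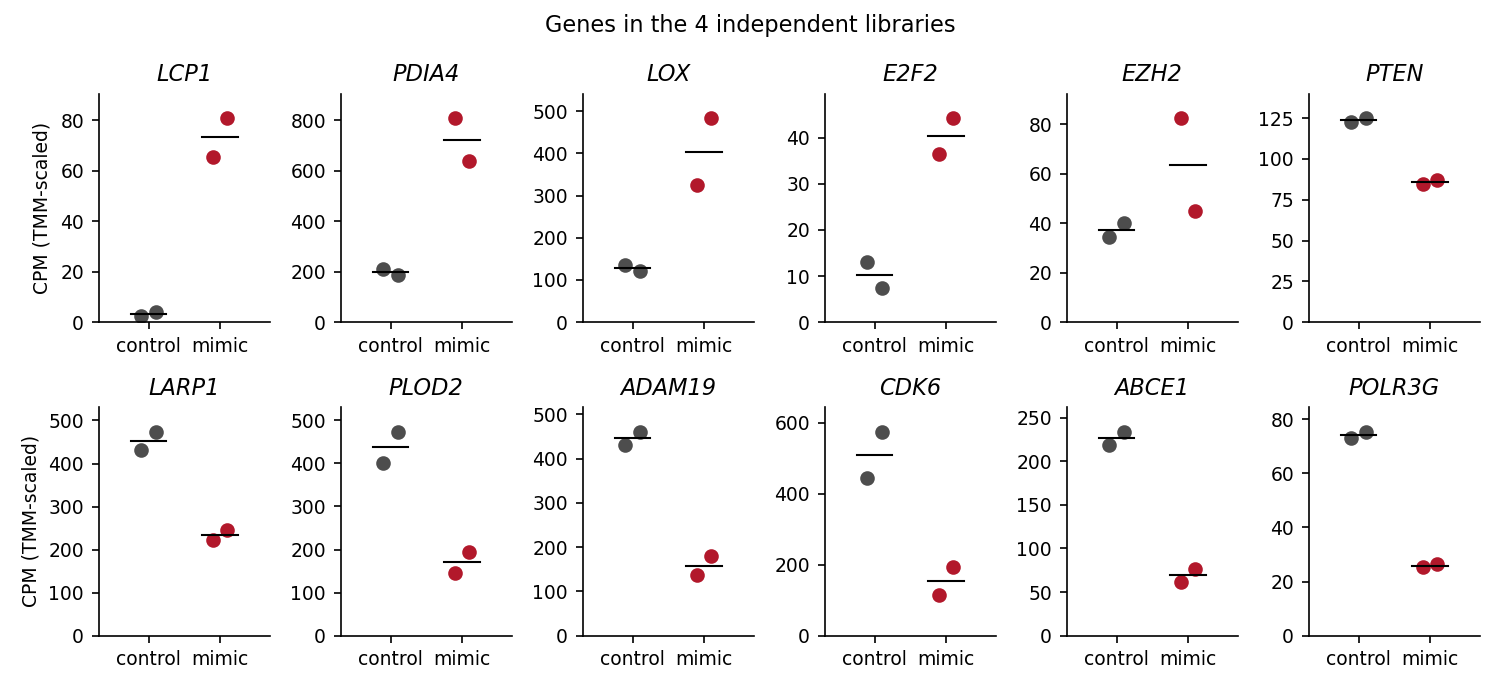
CPM, scaled by TMM, of 12 named genes in the 4 independent libraries, with control libraries in grey, mimic libraries in red and the mean of each pair as a line. LCP1 passed the test over all genes, and CDK6 went from 509 to 154 CPM.

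Genes with an 8mer site for miR-26a were lower than genes with no site. The site, TACTTGAA, was present in the 3' UTR of 760 tested genes, and 7054 had no site. Their medians differed by -0.15 on the log2 scale (95% bootstrap interval -0.20 to -0.10), with a permutation p of 1e-05, the smallest that 100000 permutations can give. Of the 8mer genes, 62.5% had a log2 fold change below 0 and 50.3% were lower in both mimic libraries, against 50.3% and 33% of genes with no site. The difference was -0.05 for 7mer-A1 genes (permutation p 0.0094), 0.02 for 7mer-m8 genes (permutation p 0.48) and 0.04 for 6mer genes (permutation p 0.0239). Site genes had longer 3' UTRs, with a median of 3206 bases for 8mer genes against 895 without a site. Against 110 length-matched genes with no site, the 8mer difference was -0.27, and over 20 draws of such genes it ran from -0.37 to -0.22. The matched differences were -0.16 for 7mer-m8, -0.24 for 7mer-A1 and -0.11 for 6mer genes. Against both controls, the 8mer difference was -0.10 in mimic 1 and -0.20 in mimic 3, and -0.27 and -0.28 against matched genes. Control 2 against control 1 gave 0.04 (permutation p 0.0004), and -0.03 against matched genes (permutation p 0.2), so a small permutation p over genes also arose with no mimic.

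**Figure D3:**
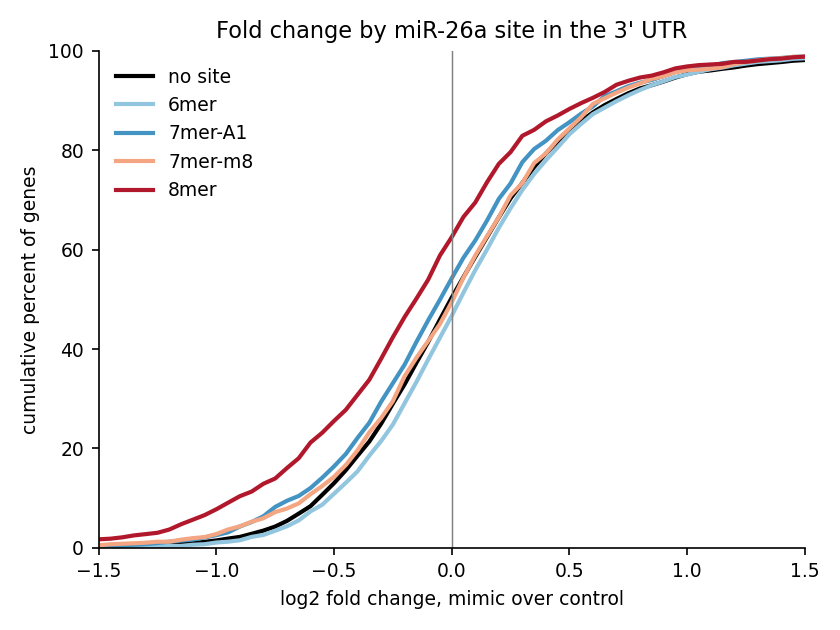
Cumulative percent of genes against the log2 fold change of mimic over control, one curve for each class of miR-26a site in the 3' UTR. The curve of the 760 genes with an 8mer site lies to the left of that of the 7054 genes with no site, with medians that differ by -0.15.

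Among 420 words with the base composition of the seed match TACTTGA, the seed match had the lowest mean difference between genes with and without it, -0.105. The next word, CTTGAAT, which overlaps the site, had -0.0594. In the coding sequence the seed match ranked 7. edgeR called no gene lower, so sites among its lower calls could not be compared. At an unadjusted p under 0.05, 470 of 1098 lower genes had a 7mer or 8mer site (42.8%). Among genes that did not reach that p, 25% had one, an odds ratio of 2.25 (Fisher's exact p 8.91e-34). Of 1118 higher genes, 264 had one (23.6%, Fisher's exact p 0.342). These tests treat genes as independent and were not matched on 3' UTR length. The sites lay in last exons. CDK6 has an 8mer on chromosome 7 at 92608045 to 92608052 and another at 92606115 to 92606122, both in exon 8 of 8. PTEN has 3 in exon 9 on chromosome 10, at 87966733 to 87966740, 87968091 to 87968098 and 87969272 to 87969279. LARP1 has one on chromosome 5 at 154817433 to 154817440, PLOD2 on chromosome 3 at 146069805 to 146069812, and EZH2 on chromosome 7 at 148807389 to 148807396.

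Genes of DNA replication lay higher and ribosomal protein genes lower. Of 58 S-phase genes, 50 had a log2 fold change above 0, 41 were higher in both mimic libraries, and the median was 0.33. Over the list alone 7 rose, among them the folate enzyme DHFR (1.13 ± 0.16), WDR76 (1.41 ± 0.20) and E2F8 (1.72 ± 0.31, SE). Camera called the list higher (adjusted p 4.13e-07), with adjusted p = 0.882 with an estimated correlation. Of 78 ribosomal protein genes, 66 lay below 0, 52 were lower in both mimic libraries, and the median was -0.27. None passed over the list alone, and RPL19 had -0.68 ± 0.19. Camera called the list lower (adjusted p 0.000132), with adjusted p = 0.882 with an estimated correlation. G2/M genes had a median of 0.15 and none of 57 passed over the list alone (camera adjusted p 0.434). No member of these lists passed over all genes tested.

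Matrix and mesenchymal genes held members that went both ways. No member of the lists below passed over all genes tested. Adjustment over a list alone was not carried across the 32 lists. Of all tested genes, 18.1% had an unadjusted p under 0.05 in edgeR, so such passes can arise in many lists. Of 53 extracellular matrix genes, 9 rose and 3 fell over the list alone (camera adjusted p 0.0622). LOX, which crosslinks collagen, went from 128 ± 10.9 to 404 ± 113 CPM (SD, n = 2), a log2 fold change of 1.66 ± 0.23 (SE). SERPINH1, a collagen chaperone, had 0.97 ± 0.17, while the basement membrane protein NID1 had -0.97 ± 0.18. Of 27 mesenchymal and EMT genes, 4 rose over the list alone, among them smooth muscle actin ACTA2 (1.60 ± 0.29) and ZEB2 (0.95 ± 0.22), and ITGA5, a fibronectin receptor subunit, fell (-1.02 ± 0.21; camera adjusted p 0.0622). Of 40 matrix proteases and inhibitors, MMP24 rose (2.95 ± 0.42) and ADAM19 (-1.49 ± 0.20) and ADAM9 (-0.98 ± 0.22) fell over the list alone (camera adjusted p 0.691). Of 17 epithelial genes, the keratins KRT8 (-1.02 ± 0.23) and KRT18 (-1.29 ± 0.21) and the junction protein TJP2 (-0.92 ± 0.16) fell over the list alone (camera adjusted p 0.617). The 17 include FZR1 (-0.22 ± 0.28), matched by alias to the listed symbol CDH1, while CDH1 itself had no row. None of 36 integrin and focal adhesion genes (camera adjusted p 0.945) and none of 61 actin and Rho genes (0.397) passed over the list alone. Stromal fibroblast markers had a median of 0.31, with COL3A1 higher over the list alone of 10 genes (1.44 ± 0.33; camera adjusted p 0.0809).

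The unfolded protein response and NF-kB lists, which cover stress of the endoplasmic reticulum and inflammation, were not called as groups. Here too, no list member named passed over all genes tested. Over the list alone of 28 unfolded protein response genes, 6 rose, among them the disulfide isomerase PDIA4 (198 ± 15.6 to 724 ± 121 CPM, SD, n = 2) and the chaperone regulator HYOU1 (0.93 ± 0.20, SE). PDIA6 (-0.78 ± 0.16) and the glutathione-degrading enzyme CHAC1 (-2.80 ± 0.37) fell over that list alone (camera adjusted p 0.111). Of 28 NF-kB and inflammatory genes, IL1B (-2.40 ± 0.53), IL1A (-1.75 ± 0.41) and the chemokine CXCL1 (-1.30 ± 0.30) fell over the list alone (camera adjusted p 0.0622). Among 24 immediate early genes, MYC fell over the list alone (-0.83 ± 0.16; camera adjusted p 0.106). In the small RNA machinery of 30 genes, AGO2 (0.87 ± 0.18) and TNRC6C (1.02 ± 0.24), both of the silencing complex, rose over the list alone, and DICER1, which cuts microRNA precursors, fell (-0.91 ± 0.18; camera adjusted p 0.887).

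No list of placental markers was called as a group by camera, and none of the list members named below passed over all genes tested. PEG10, an imprinted gene of the placenta, rose over the list alone of 15 cytotrophoblast markers (1.16 ± 0.17, SE; camera adjusted p 0.691). Of 14 extravillous trophoblast markers, TIMP3 rose (0.87 ± 0.22) and ITGA5 fell over the list alone (camera adjusted p 0.782). Only 4 of 18 syncytiotrophoblast markers with a row were tested, and none passed (0.728). Of 29 angiogenic and placental growth factors, IGF2 (13.5 ± 1.22 to 32.3 ± 2.80 CPM, SD, n = 2) and IGFBP5 (1.20 ± 0.26) rose over the list alone (camera adjusted p 0.434). OAS3 rose over the list alone of 33 interferon genes (1.10 ± 0.18, camera adjusted p 0.789), and SESN1 over that of 30 p53 targets (1.62 ± 0.30, camera adjusted p 0.728). ERG rose over the list alone of 4 endothelial markers (2.48 ± 0.63, camera adjusted p 0.782), and the other 3 lay below 0. ERG had 1.54 CPM in control 1, 0.264 CPM in control 2, below the level of 3 reads, and 5.94 and 5.56 CPM in mimic 1 and mimic 3. No gene passed over the list alone among TGF-beta and BMP genes (camera adjusted p 0.0622), PRC2 subunits (0.325), Wnt genes (0.716), YAP and TEAD targets (0.434), PI3K, AKT and mTOR genes (0.434), cholesterol synthesis genes (0.434), blood and immune markers (0.75) or squamous and other epithelial markers (0.506).

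The mimic libraries also differed from each other. Mitochondrially encoded mRNAs took 5.46% of gene-row reads in mimic 1 and 2.47% in mimic 3, against 3.41% in control 1 and 2.77% in control 2. The median log2 ratio of these 13 mRNAs to the controls was 0.73 in mimic 1 and -0.46 in mimic 3 (camera adjusted p 0.506). Hypoxia and glycolysis genes had a median of -0.37 in mimic 1 and 0.29 in mimic 3 (camera adjusted p 0.782), with the carbonic anhydrase CA9 at 5.31 CPM in mimic 1, 24.6 CPM in mimic 3 and 3.81 ± 0.91 CPM (SD, n = 2) in the controls. Neither list had a gene past the threshold over the list alone. Against the same controls, the medians in mimic 1 and mimic 3 were -0.41 and -0.29 for reported targets, 0.34 and 0.30 for S-phase genes, and -0.30 and -0.25 for ribosomal protein genes. Shared controls make such values alike in part. In pairs that share no library, chosen after the values were seen (mimic 1 over control 1, mimic 3 over control 2), they were -0.36 and -0.29, 0.36 and 0.34, and -0.39 and -0.17. Of all 13758 tested genes, 33.9% were higher and 33.7% lower in both mimic libraries, against 59% of reported targets lower, 70.7% of S-phase genes higher and 66.7% of ribosomal protein genes lower.

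**Figure D4:**
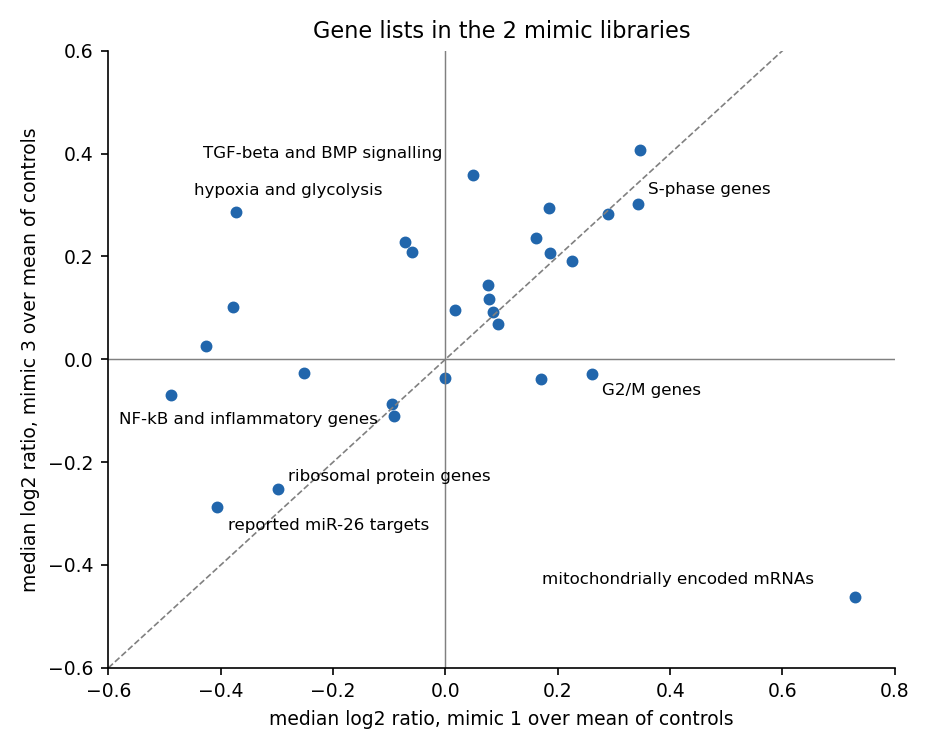
Median log2 ratio to the mean of the controls of each gene list with at least 10 tested genes, in mimic 1 (x axis) and mimic 3 (y axis), one point per list, with the dashed line marking equal values. Mitochondrially encoded mRNAs lie at 0.73 and -0.46, and reported miR-26 targets at -0.41 and -0.29.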

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

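The fit of all 6 libraries was the one planned, and the main fit of 2 libraries per group was chosen after seeing the data. Alternatives that keep mimic 2 as a separate library or the circular RNA rows, or leave out control libraries 1 and 3 together, were also chosen then. So were those that take an adjusted p under 0.1, use unadjusted calls, test single libraries or compare lists in library pairs that share none. edgeR called 4 genes higher and 0 lower with 2 libraries per group, and also with DESeq2's size factors, upper quartile scaling, the stricter filter and the non-robust prior. It called 587 higher and 558 lower with no filter on low counts, 747 and 725 with mimic 2 kept, and 1900 and 1764 with all 6 libraries counted as separate. Without control libraries 1 and 3 it called 6 higher and 0 lower. With circular RNA rows kept it called 0 higher and 0 lower gene rows. At an adjusted p under 0.1 it called 16 higher and 3 lower, and DESeq2 called 143 higher and 136 lower, leaving 1868 genes without an adjusted p. Leaving out a library gave between 0 and 2204 higher and between 0 and 2362 lower. The highest counts came without a mimic library, where the lone mimic library is assumed to vary like the controls, and leaving out mimic 2 is the reported fit. Fits with mimic 2 kept or all 6 libraries count libraries that are not independent as separate samples, so their p-values are too small. The common biological coefficient of variation was 0.198 in the main fit and 0.133 with all 6 libraries. For the remaining alternatives the cause was not tested.

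The replicate block was fitted to all 6 libraries, again counted as separate, and called 1596 higher and 1446 lower. Deviations of same-numbered libraries from their group means correlated at 0.109, 0.00094 and -0.038. Since the 6 libraries did not hold 6 separate sets of reads, these values cannot decide whether the numbers pair the samples.

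The 8mer difference kept its direction and its side of the threshold under every alternative tested. It was -0.272 with length-matched genes and -0.078 for mimic 1 against control 1 over all genes. It reached -0.315 for mimic 3 against control 2 with matched genes and -0.367 in 1 of 20 draws of matched genes, and ran from -0.198 to -0.0964 with a library left out. The seed word ranked 1 with a length and GC trend removed and 7 in the coding sequence. Genes with a 7mer or 8mer site numbered 470 lower and 264 higher at an unadjusted p under 0.05. With all 6 libraries counted as separate, they numbered 681 of 1699 lower genes (40.1%) and 393 of 1623 higher genes (24.2%), against 24.3% of genes not called. At an absolute log2 fold change of at least 1 they numbered 115 of 220 lower (52.3%) and 98 of 461 higher (21.3%). Fry, the list test planned alongside camera, gave an adjusted p of 0.184 for each of reported miR-26 targets, S-phase genes and ribosomal protein genes. None of the 3 passed with it. These lists kept their camera calls except with an estimated correlation, where the adjusted p was 0.882 for each. With a library left out their adjusted p ran from 4.25e-07 to 0.000804, from 4.49e-08 to 2.34e-05 and from 1.53e-07 to 0.000445.

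Other lists passed under some alternatives. Fits with mimic 2 kept, all 6 libraries or the replicate block count libraries that are not independent as separate samples. Passing in them is therefore no independent support for a list. For the other alternatives the cause was not tested. Extracellular matrix genes passed with mimic 2 kept (0.0426), all 6 libraries (0.0362), the replicate block (0.0449) and limma-voom (0.0473), and TGF-beta and BMP genes likewise (0.0389, 0.0117, 0.0449 and 0.0408). EMT genes (0.0484) and the unfolded protein response (0.0437) passed with the replicate block. NF-kB genes passed with no filter (0.0299), without both control libraries 1 and 3 (0.00209) and with circular RNA rows (0.0311), immediate early genes with circular RNA rows (0.0387), and stromal markers with no filter (0.0443) and without control libraries 1 and 3 (0.0248), as did EMT genes there (0.033). With a library left out, adjusted p ran from 0.000377 to 0.485 for extracellular matrix, 0.00529 to 0.259 for EMT, 0.000757 to 0.92 for angiogenic factors, 0.00457 to 0.701 for G2/M, 0.000133 to 0.828 for TGF-beta and BMP, 0.000639 to 0.118 for the unfolded protein response, 0.0271 to 0.619 for cholesterol synthesis, 0.000327 to 0.906 for hypoxia and glycolysis, 0.000979 to 0.584 for immediate early genes, 9.55e-07 to 0.947 for mitochondrial mRNAs, and 0.0303 to 0.352 for stromal markers. Hypoxia and glycolysis was called higher without mimic 1 (0.000327) and lower without mimic 3 (0.000475). Mitochondrial mRNAs were called lower without mimic 1 (2.87e-05) and higher without mimic 3 (9.55e-07). Over named genes and alternatives, 1856 values stayed on the same side of the threshold, 727 passed it and 9 no longer did, all 9 for the called genes. In the simulated counts, 44% of 2-fold changes were recovered, but changed genes there were well counted and spread did not vary between genes of 1 level. Recovery in the real counts can therefore be lower.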

Other observations

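The tests of the reused reads, of mimic activity, of the called genes and of other splits were chosen after the results were seen. Genes with an adjusted p under 0.1 in edgeR's quasi-likelihood test, 16 higher and 3 lower, were examined after their values were seen. Of the 3 lower ones, the ribosome recycling factor ABCE1 went from 227 ± 10.7 to 69.1 ± 10.6 CPM, the initiation factor EIF4G2 from 1232 ± 91.7 to 448 ± 39.3 CPM, and the RNA polymerase III subunit POLR3G from 74.3 ± 1.64 to 25.9 ± 0.83 CPM (SD, n = 2). ABCE1 has an 8mer site in its 3' UTR on chromosome 4 at 145128790 to 145128797, POLR3G has 8mer sites on chromosome 5 at 90512445 to 90512452 and 90512791 to 90512798, and EIF4G2 has a 7mer-m8 site. Among the 16 higher were PDIA4, the potassium channel KCNC3 (log2 fold change 2.37 ± 0.26, SE), the scramblase PLSCR4 (2.66 ± 0.30), the guidance cue NTN1 (1.83 ± 0.23) and the cadherin FAT4 (1.42 ± 0.18).

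The median log2 ratio to the controls in mimic 1 and mimic 3 was 0.45 and 0.02 over 897 unnamed long noncoding RNAs, 0.34 and 0.125 over 546 named ones, and -0.04 and -0.00 over 12274 protein-coding genes. At an unadjusted p under 0.05 in edgeR, 119 unnamed ones were higher and 17 lower, and 72 named ones were higher and 11 lower. Differences between these classes were not tested. Of 15053 circular RNA rows tested with edgeR, 0 were called higher or lower, with 271 higher and 242 lower at an unadjusted p under 0.05. No other tool was run on them.

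Control library 3 and mimic library 2 lay closer to other libraries than separate libraries of the same RNA would. Control 3 divided by 2 exceeded control 1 in 4 of 19819 genes, against at least 239 in 20 simulated separate draws. Mimic 2 exceeded the sum of mimic 1 and mimic 3 in 3 genes, against at least 210. A candidate explanation is that reads of other libraries were used again, about 45.5% of control 1 counted 2 times in control 3, and about 43.6% of mimic 1 and 37% of mimic 3 in mimic 2. The sources used here give no step at which this arose, and no biological explanation was tested.

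Mimic libraries 1 and 3 lay far apart, with an SD of log2 ratios of 0.531 over 8496 genes against 0.228 for the control pair. The ratio of these SDs was 2.13 after removing a trend on GC content and length and 2.2 after thinning all 4 libraries to 1 depth, which argues against both as the whole cause. The log2 ratio of mimic 1 to mimic 3 did correlate with GC content of the coding sequence, at -0.415 (Spearman). More mimic activity in mimic 1 could not be decided. The 8mer genes in mimic 1 differed from those in mimic 3 by 0.0035 against length-matched genes. Over 20 draws of matched genes this difference ran from -0.0455 to 0.137, and its intervals reached from -0.177 to 0.312. Against all genes with no site, not matched on length, it was 0.098 (95% bootstrap interval 0.0385 to 0.136), opposite to more activity in mimic 1. A difference between the cultures may remain, and was not tested.

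Of technical explanations for the 4 genes called higher, blood cells are argued against by PTPRC and LAPTM5, leukocyte genes that would come with LCP1 from such cells and together reached at most 4.19 CPM in a library (not scaled by TMM). More nuclear RNA would raise MALAT1 and NEAT1, and the higher of their log2 fold changes was 0.255. RN7SK, another nuclear RNA, had 0.45 ± 0.28 (SE), and its share of gene-row reads was 2.92% and 2.95% in control 1 and control 2, 4.43% in mimic 1 and 3.66% in mimic 3, far below the fold changes of the called genes. Transcription running in from a neighbour would need one to rise alike, and the highest of the tested neighbours within 60 kb, ANGPTL4, had 1.13, while LCP1 had none. A response to the mimic stays open as a hypothesis, and none of the 4 was shown to be a direct target.

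Splits of the libraries are too few for a share under 0.05. For 4 libraries, 1 of 3 splits gave as many calls, the real one with 4, and the highest other gave 0. For all 6 libraries, 1 of 10 splits did, the real one with 3664, and the highest other gave 0. With a trend on length and GC content removed, the seed word still ranked 1 of 420 words. This argues against lower counts of long 3' UTRs or of AT-rich words as the whole cause. The seed word has 7 bases and 1733 genes held it, so its rank does not measure the 8mer difference alone. Against length-matched genes the 8mer difference was -0.27.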
